A study of Homo sapiens with 6 samples.

How the data were processed

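Messenger RNA was measured by RNA sequencing in 6 libraries labelled MCF7, 2 each of a control with a control hairpin, an AF9 knockdown and a sodium oxamate treatment. Per the labels' protocols, total RNA was extracted with a column kit (TIANGEN RNAsimple), and libraries were made from 1 µg with an MGIEasy kit. Samples were grouped by their titles and library names. The design text of the series also names cells with extra AF9, which have no file here and are not analysed here.

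The deposited values are expected counts per gene, 1 file per library, with Entrez gene identifiers and no header. Per the submitters' processing notes, reads were aligned to hg38 and the tools named are HISAT2 2.1.0, SAMtools without a version and HTSeq 2.0.3, with no role, order or options stated. Strand setting, annotation and gene filter are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. Between 44.9 and 46.9% of the deposited counts per file are not whole numbers, with up to 2 decimals, although HTSeq usually gives whole counts; the step that split reads between genes is not recorded, and close paralogs may share reads. The test design was fixed for raw counts before the files were seen, and the deposited expected counts were rounded to whole numbers for it. Symbols and coordinates were taken from a RefSeq gene table of GRCh38.p14, the same build, which matched 15889 of 15890 identifiers. No mitochondrially encoded gene is listed.

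The files list 15890 genes, of which 81 had a count of 0 in all libraries. Genes were kept by edgeR's filterByExpr with a count minimum of 10 and a total minimum of 15, which left 12734. Counts were scaled by TMM factors, which ran from 0.944 to 1.055, and CPM values are scaled by them. Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, 1 mean per group, all 6 libraries in 1 fit, 3 residual degrees of freedom) with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. The comparisons were AF9 knockdown against control, sodium oxamate against control and sodium oxamate against AF9 knockdown. The standard error of a log2 difference is its size divided by the square root of F. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes and again with an estimated correlation. Before the files were seen 32 lists with 936 genes were fixed, of which 880 genes are listed; 30 lists with at least 5 tested members were tested and 2 were too small. The p-values of the lists were adjusted over these 30.

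After the fold changes were found to follow GC content, a correction was added. The GC content of each gene was taken from GENCODE 29 transcripts and was known for 99.8% of the tested genes (12703). Each gene's log2 CPM was centred on its mean over the libraries. For each library a loess curve (span 0.3) of these centred values on GC content was used as an offset in the same edgeR fit. DESeq2 1.42.0 was run with its own size factors and again with the GC trend in its normalization factors.

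The genes named were chosen by a rule written before the files were seen. MLLT3 and KLF2 are given in each comparison, and LDHA and LDHB for oxamate against control. For each comparison against control the rule takes the 8 higher and the 8 lower genes with the largest log2 difference among those past the threshold, with a mean of at least 5 CPM in the higher group and both libraries of a group above both of the other. It adds up to 4 members with the smallest p-values of each list past the threshold, and the 5 genes per direction called in both comparisons with the smallest larger p-value. Where no gene passed, the 5 with the smallest p-values per direction are given and said to be not past the threshold. Members of 3 lists that did not pass were also named, and the text says that they were chosen after their values were seen.

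The total count per library was 20789334 to 21100017, a ratio of 1.015. At this depth 1 count is 0.045 to 0.05 CPM, and a count of 100 has a Poisson standard deviation of 10%; both cover counting error only. The 10 genes with the most counts took 5.7 to 7.66% of a library.

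The scripts were tested on simulated counts drawn from the means, library sizes and dispersions of the real data, with 100 genes changed 2-fold and 100 changed 1.5-fold. For AF9 knockdown against control, with 12587 genes tested, edgeR recovered 95 of 100 genes changed 2-fold and 56 of 100 changed 1.5-fold, and called 23 of 12359 unchanged genes. For sodium oxamate against control, with 12583 genes tested, it recovered 96 and 55 of 100 and called 12 of 12354 unchanged genes. When the measured GC trend of the libraries was added, the uncorrected fit called 2750 of 12368 unchanged genes for the AF9 knockdown (12597 tested) and the corrected fit 12, while for oxamate (12583 tested) it called 282 of 12353 and the corrected fit 16. With that trend the corrected fit recovered 98 and 50 of 100 genes for the AF9 knockdown and 98 and 55 for oxamate. Each simulated gene had 1 dispersion for all groups. Real pairs differed in spread (chi-square per degree of freedom 3.06 in control, 43.78 in the AF9 knockdown and 12.94 under oxamate). The simulated recoveries therefore do not give the sensitivity for the real libraries. In the same simulations the list of immediate early genes, lowered 1.5-fold, was found lower by camera, and of 29 other lists 0 passed without the trend. With the trend 1 of the 29 passed in the uncorrected fit of each comparison and 0 in the corrected fit. The simulated genes were drawn independently of each other. These runs therefore cannot show how the preset correlation serves lists whose members vary together. The estimated correlation, which rests on 3 residual degrees of freedom, was not tried in these runs. Whether it can find a changed list was therefore not shown.

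Shared controls were treated by simulating unchanged groups against the real controls 20 times. The alternatives tried were RLE scaling, no scaling beyond totals, no filter beyond at least 1 count, DESeq2, a robust fit, only the 4 libraries of a comparison, the replicate number as a block, each library left out in turn and, added after the data were seen, the GC correction with its own alternatives (transcript length, replicate block, DESeq2, RLE scaling, a span of 0.5 and each library left out). A library left alone in its group was assumed to vary like the other groups. P-values and gene counts of such fits therefore hold no spread measured in that group. No samples were left out of the main tests.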

Results

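Polyadenylated RNA was sequenced from 6 libraries labelled MCF7, an established human breast cancer line known as luminal and estrogen receptor positive. The libraries fell into 3 groups of 2. The control carried a control short hairpin RNA, a construct that lowers no intended target. The AF9 knockdown carried a hairpin against AF9, a reader of acylated histones that is encoded by MLLT3. The sodium oxamate group carried the control hairpin, per the library names, and was exposed to oxamate, an inhibitor of lactate dehydrogenase. The title of the series names a circuit of AF9 and the transcription factor KLF2, histone lactylation (lactyl groups on histones) and metastasis of breast cancer. Total counts ran from 20789334 to 21100017 per library, and between 14717 and 15008 genes had a count in each. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicates differed beyond sampling noise, with a chi-square per degree of freedom of 3.06 in the control, 43.78 in the AF9 knockdown and 12.94 under oxamate, so none was counted as a duplicate.

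Several genes that mark luminal breast cells were close to the floor in all 6 libraries, while others were not. ESR1, the estrogen receptor, had 7 to 31 counts per library, GATA3, a luminal transcription factor, had 0 to 3, KRT19, a luminal keratin, had 0 to 3, and PGR, the progesterone receptor, had 0 to 1. CDH1, the epithelial cadherin, had 10 to 24 counts. The intermediate filament gene VIM averaged 1540 CPM (counts scaled to a fixed library total), the receptor tyrosine kinase gene AXL 247 CPM and the adhesion receptor gene CD44 344 CPM, beside 1810 CPM for the epithelial keratin KRT8 and 1080 CPM for KRT18. Not all mesenchymal genes were high: FN1 had 25 to 32 counts (mean 1.38 CPM) and ZEB1 averaged 16.8 CPM. Of 35 listed members of the mesenchymal and invasion list, 7 had a mean under 1.5 CPM and 23 a mean over 10 CPM. The luminal transcription factor gene XBP1 was at 118 to 148 CPM and the mucin gene MUC1 at 91 to 240 CPM. Of the fixed lists, 11 of 34 luminal and 8 of 27 epithelial members that the files list had a mean under 1.5 CPM, and 18 and 14 had a mean over 10 CPM (medians 13.2 and 27.3 CPM). The single genes were chosen after their values were seen. The samples are therefore called the libraries labelled MCF7 wherever the line matters.

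**Figure D1:**
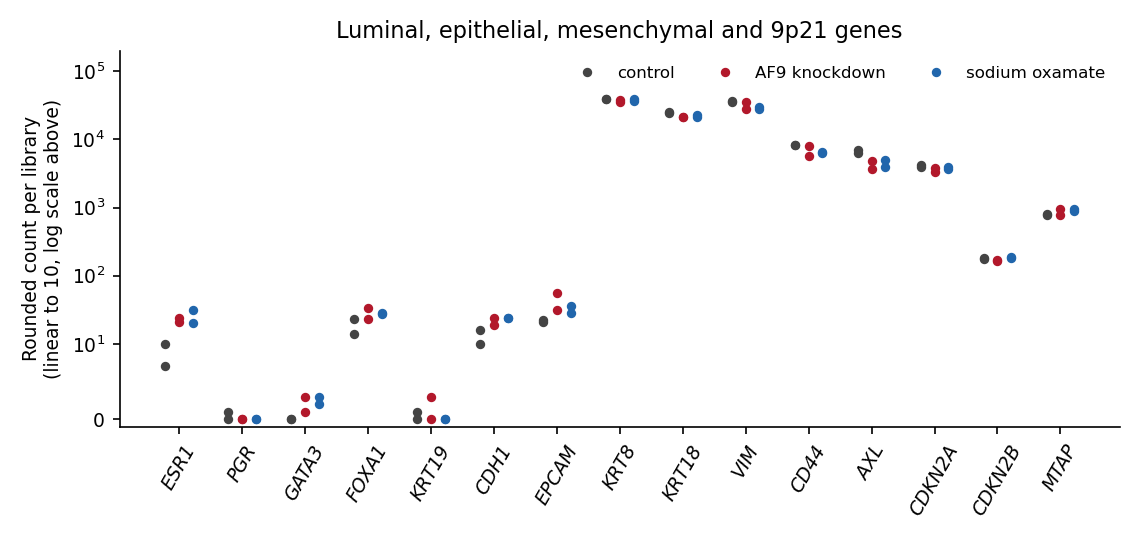
Rounded counts per library (y axis, linear up to 10 and logarithmic above) of luminal, epithelial, mesenchymal and chromosome 9p21 genes (x axis); each point is 1 library, coloured by group, with 2 libraries per group. ESR1 lies at 7 to 31 counts and VIM at 27900 to 36475 in all 6 libraries.

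The comparison of AF9 knockdown with control asked which genes change when AF9 is lowered. MLLT3 itself (Entrez 4300; GRCh38 chromosome 9, 20341669 to 20622499) was at 35.7 and 36.5 CPM in the control libraries, 22.4 and 23.9 CPM in the AF9 knockdown and 36.8 and 34.2 CPM under oxamate. It fell by 0.64 on the log2 scale in the knockdown (standard error 0.123, n = 2 per group, edgeR adjusted p = 0.0127), a 1.56-fold reduction. KLF2 (Entrez 10365; chromosome 19, 16324826 to 16328685) was at 5.75 and 5.34 CPM in control, 4.14 and 3.17 CPM in the knockdown and 3.77 and 4.66 CPM under oxamate. Its log2 difference in the knockdown was -0.60 (standard error 0.221) and did not pass the threshold (edgeR adjusted p = 0.0586). The MLLT3 call was lost without control replicate 1 (log2 difference -0.66) or control replicate 2 (-0.63). The KLF2 difference was -0.81 without AF9 knockdown replicate 1 and -0.41 without AF9 knockdown replicate 2. With 1 library left in a group, the fit measures no spread there. A correction for the GC content of transcripts, described with the GC trend, moved MLLT3 to -1.11 (edgeR adjusted p = 0.0269) and KLF2 to -0.18 (0.54).

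**Figure D2:**
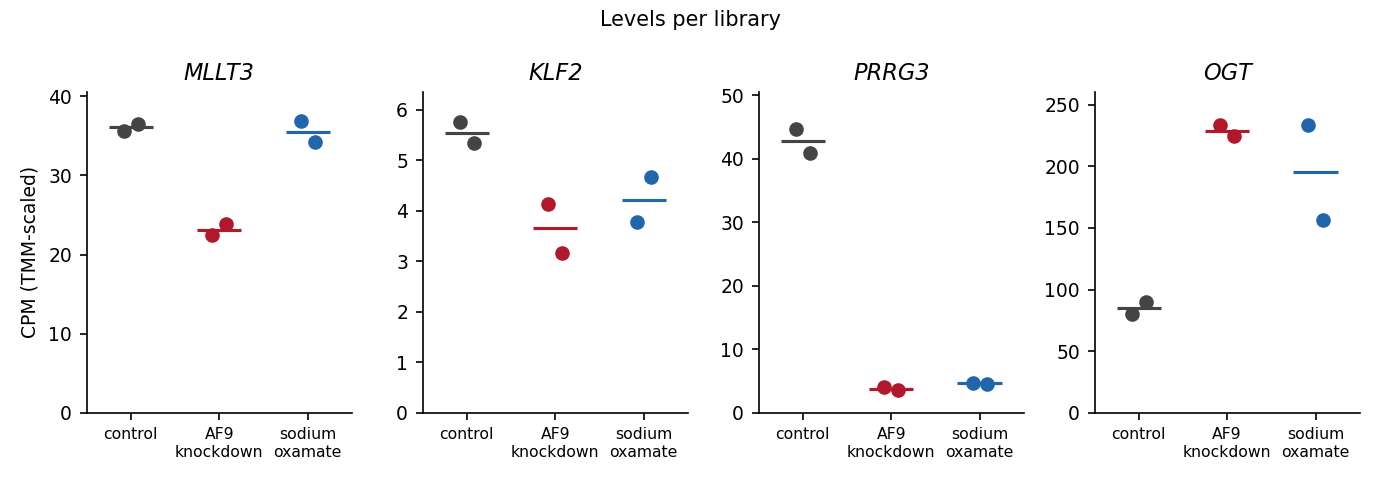
Level of MLLT3, KLF2, PRRG3 and OGT in CPM after TMM scaling (y axes, each starting at 0) in the 3 groups (x axis); each point is 1 library and each bar the mean of 2. PRRG3 lies at 40.8 and 44.7 CPM in control and between 3.53 and 4.70 CPM in the other 4 libraries.

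The steepest fall in the AF9 knockdown among the genes named by the fixed rule was in PRRG3 (Entrez 79057; chromosome X, 151694607 to 151705924), which encodes a membrane protein with a vitamin K-dependent Gla domain. It dropped from a mean of 42.8 CPM to 3.76 CPM, 11.4-fold (log2 difference -3.51, standard error 0.161, edgeR adjusted p = 8.03e-06). NDRG1, a gene induced by hypoxia, fell by 1.54 on the log2 scale from 5877 and 6601 CPM to 2862 and 1419 CPM. SERPINE1, the plasminogen activator inhibitor, fell by 1.54, ITGB4, an integrin subunit of hemidesmosomes, by 1.38, and the stress response gene IER3 by 1.41. SPINK6, a serine protease inhibitor, NEURL1B, a ubiquitin ligase gene, and B3GALT4, a ganglioside synthesis gene, fell by 1.71, 1.53 and 1.46. Of the 8 largest rises, PAPPA2, a protease that cleaves insulin-like growth factor binding proteins, gained 1.54 (167 and 284 CPM against 87.2 and 67.7) and IGFL4, an insulin growth factor-like gene, 1.69. The myosin gene MYO1A (2.54), ZNF485 (2.03), the mitochondrial gene GDAP1 (1.63), FERRY3 (1.54) and the DNA ligase gene LIG4 (1.53; 1.02 with the GC correction) also rose. NRSN1 rose by 5.05, but mainly in AF9 knockdown replicate 1, at 35.9 CPM against 2.67 CPM in replicate 2. Without AF9 knockdown replicate 1 the difference was 2.20 for NRSN1, 0.87 for ZNF485, -2.60 for NEURL1B, -2.41 for SERPINE1 and -3.13 for SPINK6. Without replicate 2 it was 1.01 for FERRY3, 0.82 for GDAP1, 0.88 for LIG4, 1.27 for MYO1A, -0.90 for NEURL1B, -0.99 for SERPINE1 and -0.98 for SPINK6. In the robust fit NRSN1 (edgeR adjusted p = 0.126), SPINK6 (0.0818) and SERPINE1 (0.0657) lost their calls, as did those genes, NEURL1B and ZNF485 with only the 4 libraries compared, and SPINK6 in DESeq2 (adjusted p = 0.0834).

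Of the 30 fixed gene lists with enough tested members, 5 were lower in the AF9 knockdown by camera with its preset correlation, and all 5 calls were lost when the correlation was estimated. Immediate early genes, which respond within minutes to growth signals, had 18 of 30 members lower and 0 higher (19 lower adjusted over the list alone), with a median log2 difference of -0.52 (camera adjusted p = 2.34e-06; adjusted p = 0.81 with an estimated correlation). IER3, the AP-1 subunit gene JUNB (-1.02) and the ETS factor genes ETV4 (-1.06) and ETV5 (-1.07) were among them. Genes of glycolysis and lactate handling had 21 of 33 members lower and 3 higher (21 and 4 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00166; adjusted p = 0.81 with an estimated correlation). The pyruvate kinase gene PKM fell by 0.63, the hexokinase gene HK1 by 0.62, the lactate transporter chaperone gene BSG by 0.67 and the pyruvate dehydrogenase kinase gene PDK2 by 0.67. In edgeR the GC correction ended the calls of all genes named for these lists. It moved PKM to -0.30, BSG to -0.27, PDK2 to -0.31, JUNB to -0.60 and ETV4 to -0.69 (edgeR adjusted p from 0.0755 to 0.138 for these 5). ETV5 was then at -1.10, IER3 at -1.08 and HK1 at -0.45. DESeq2 with the same trend still called the genes named for these lists except BSG (adjusted p = 0.0743) and PDK2 (0.194).

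Mesenchymal and invasion genes had 9 of 29 members lower and 0 higher (10 lower adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.0145; adjusted p = 0.81 with an estimated correlation). Among them were the lysyl oxidase gene LOXL2 (-1.07), the urokinase receptor gene PLAUR (-0.71), the growth factor gene TGFB1 (-0.73) and TGFBI (-1.05), a matrix gene it induces. Hypoxia response genes had 12 of 34 members lower and 3 higher (15 and 3 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0366; adjusted p = 0.822 with an estimated correlation). NDRG1, LOXL2 and the circadian repressor gene BHLHE40 (-0.92) fell while the ubiquitin ligase adaptor gene WSB1 rose by 0.71. Replication-dependent histone genes, whose transcripts as a rule carry no poly(A) tail, had 6 of 22 members lower and 0 higher (6 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.0302; adjusted p = 0.81 with an estimated correlation). The linker histone genes H1-2 (-1.21) and H1-4 (-1.46), and H2BC21 (-1.04) and H2BC5 (-0.85), were lower. DESeq2 gave no adjusted p for H1-4. Of the 46 members of this list in the files, 42 had a mean under 1.5 CPM (median 0.367 CPM). This list was fixed beforehand as a sign of library preparation, and it was lower in both groups set against control, beside the other 4 lists. In edgeR the GC correction ended the calls of all genes named for these 3 lists. It moved TGFB1 to -0.33, PLAUR to -0.45 and WSB1 to 0.34 (edgeR adjusted p = 0.103, 0.0799 and 0.146). H2BC21 was then at -1.10, H2BC5 at -0.93, BHLHE40 at -0.79 and TGFBI at -0.84. DESeq2 with the same trend still called LOXL2, PLAUR, TGFBI, BHLHE40, H1-2 and H2BC21, but not TGFB1, NDRG1, WSB1 or H2BC5. Some lists fixed as markers of other cell types had low medians too without passing: -0.53 for basal breast epithelium and -0.43 for fibroblasts, each with 10 tested (camera adjusted p = 0.222 for both). With the GC correction they were -0.32 and -0.18. The leukocyte list, with 6 tested, had a median of -0.23 before and 0.12 after the correction and passed neither time (camera adjusted p = 0.594 and 0.921). Immediate early, glycolysis and hypoxia genes also lay lower in AF9 knockdown replicate 2 than in replicate 1, with GC-corrected medians of replicate 2 minus replicate 1 of -0.30, -0.24 and -0.63.

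The lists closest to the title of the series did not pass as groups in either comparison against control. For scale, 32.4% of all 12734 tested genes were called in the AF9 knockdown and 10.1% under oxamate. Of 22 members of AF9 complexes, 3 were higher and 7 lower in the AF9 knockdown (4 and 8 adjusted over the list alone; median -0.16, camera adjusted p = 0.419), and under oxamate 1 was higher and 0 lower (1 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.307). The 7 lower members in the knockdown include MLLT3, the gene knocked down. Members named after their values were seen were the cyclin gene CCNT2 of the elongation factor P-TEFb, which rose by 1.06 in the knockdown and 1.00 under oxamate, and the histone methyltransferase gene DOT1L, which fell by 0.44 in the knockdown. Of 14 KLF transcription factors, 1 was higher and 3 lower in the knockdown (2 and 6 adjusted over the list alone; median -0.12, camera adjusted p = 0.426), and 0 and 1 under oxamate (0 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 0.0852). Of 11 genes linked to KLF2 in endothelial and immune cells, 3 were lower in the knockdown (CDKN1A, ASS1 and ITPR3, also named after the fact; median -0.19, camera adjusted p = 0.324) and 2 under oxamate (CDKN1A and ITPR3; median -0.15, camera adjusted p = 0.418). Adjusted over the list alone these were 3 lower in the knockdown, and 4 lower and 1 higher under oxamate. Enzymes linked to histone acylation had 1 of 26 higher and 6 lower in the knockdown (1 and 6 adjusted over the list alone; median -0.13, camera adjusted p = 0.234), and 1 and 1 under oxamate (1 and 1 adjusted over the list alone; median -0.10, camera adjusted p = 0.203). The deacetylase gene HDAC2 was the higher member in both (0.69 and 0.50), and the acetyltransferase gene KAT5 was lower in both (-0.70 and -0.61), again named after the fact. With the GC correction edgeR kept none of these single-gene calls apart from MLLT3, and after it the KLF list passed as lower under oxamate (median -0.20, camera adjusted p = 0.0155; adjusted p = 0.579 with an estimated correlation).

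In all, 2138 genes were higher and 1986 lower in the AF9 knockdown among 12734 tested by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 250 and 98 changed at least 2-fold. With no scaling beyond library totals the split was 71.6% higher against 51.8% with TMM, and the median of all genes lay at 0.125 in place of 0.016. The counts of higher and lower genes were 46 and 56 without control replicate 1, 96 and 55 without control replicate 2, 3322 and 3242 without AF9 knockdown replicate 1, 1424 and 1198 without oxamate replicate 1, and 1446 and 1210 without oxamate replicate 2. Of the 40 named genes past the threshold besides MLLT3, 39 lost the call with the GC correction (all but PRRG3). Of these 39, 27 stayed within 1.5 times their log2 difference, such as PAPPA2 at 1.52, IGFL4 at 1.68 and MYO1A at 2.69, and 29 were called by DESeq2 with the same trend. Of the 40, 14 lost the call without control replicate 1, 17 without control replicate 2, 1 without AF9 knockdown replicate 2, and 6 each without oxamate replicate 1 or 2.

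Fold changes against control followed the GC content of the transcripts. Tested genes were split by GC content into 10 groups of about the same size. In the GC-poorest group, with 30.2 to 38.8% GC, 590 genes were higher and 3 lower in the AF9 knockdown, and 185 and 1 under oxamate. In the GC-richest group, with 62.3 to 74.7% GC, 3 were higher and 588 lower in the knockdown, and 0 and 150 under oxamate. Across genes, which are not independent replicates, Spearman's rho of the log2 difference with GC content was -0.703 for the AF9 knockdown, -0.636 for oxamate and 0.432 for oxamate against AF9 knockdown. Libraries of the same group also differed along GC content, with a rho for replicate 2 minus replicate 1 of -0.22 in control, -0.267 in the AF9 knockdown and 0.648 under oxamate. With each library's GC trend removed, a step added after the data were seen, edgeR called 0 genes higher and 2 lower in the AF9 knockdown (PRRG3 and MLLT3) among 12703 tested, with 3232 at an unadjusted p below 0.05. Under oxamate it called 0 higher and 3 lower (PRRG3, IGFBP1 and H1-2, the last lost at an adjusted p of 0.0554 when transcript length was corrected as well), with 2699 at an unadjusted p below 0.05, and DESeq2 with the same trend called 329 and 453, and 216 and 377. At an adjusted p below 0.1 the GC-corrected edgeR fit held 469 genes higher and 534 lower in the knockdown, and 56 and 112 under oxamate. The correction took the median absolute log2 difference of the uncorrected calls from 0.59 to 0.24 in the knockdown and from 0.63 to 0.39 under oxamate, and their median standard error from 0.147 to 0.112 and from 0.146 to 0.11.

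The GC-corrected edgeR counts also rested on the spread of the AF9 knockdown pair, which the fit pools over groups. Without AF9 knockdown replicate 1 they were 2539 higher and 2939 lower for the knockdown and 1752 and 2169 for oxamate. Without AF9 knockdown replicate 2 they were 973 and 1216, and 1762 and 2125. With any 1 of the 4 other libraries left out, 0 genes were higher and 1 was lower (PRRG3) in either comparison, so that MLLT3, IGFBP1 and H1-2 lost their calls. The 5 lists lower in both comparisons against control stayed past the threshold after the correction with camera's preset correlation, with medians for the AF9 knockdown of -0.42 for immediate early, -0.30 for glycolysis, -0.39 for hypoxia, -0.29 for mesenchymal and -0.25 for histone genes. With an estimated correlation none did (smallest adjusted p = 0.673 for the knockdown and 0.579 for oxamate).

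**Figure D3:**
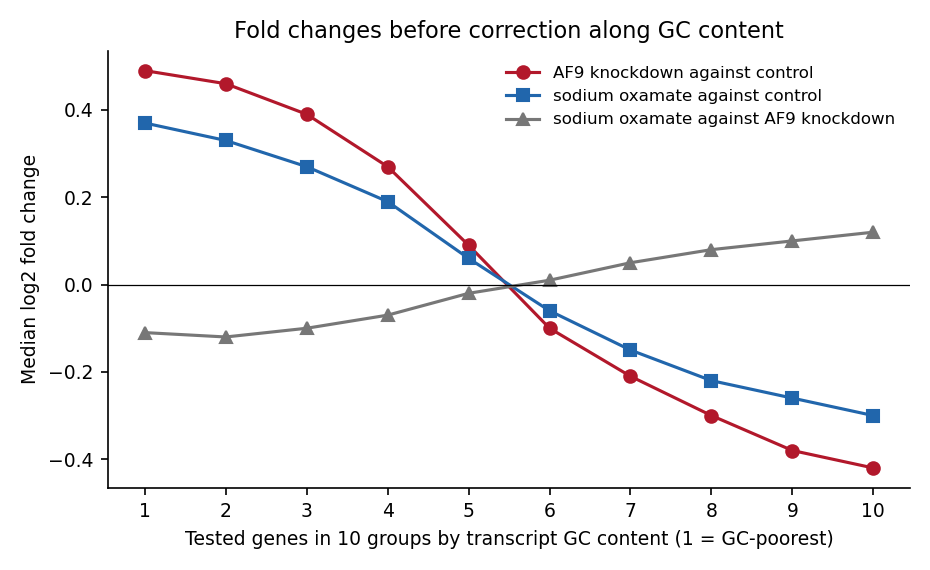
Median log2 fold change before GC correction (y axis) of the tested genes in 10 groups by transcript GC content (x axis, GC-poorest first) for the 3 comparisons, each of 2 libraries against 2. The AF9 knockdown against control runs from 0.49 in the poorest to -0.42 in the richest group, and oxamate against control from 0.37 to -0.30.

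The comparison of sodium oxamate with control asked which genes change when lactate dehydrogenase is inhibited. The genes of the enzyme's subunits are LDHA (Entrez 3939; chromosome 11, 18394563 to 18408425) and LDHB (Entrez 3945; chromosome 12, 21635342 to 21657842). LDHB rose by 0.52 on the log2 scale (standard error 0.144, n = 2 per group, edgeR adjusted p = 0.0479), from 905 and 920 CPM to 1454 and 1167 CPM. LDHA, at 4247 and 4633 CPM in control and 3887 and 3862 CPM under oxamate, differed by -0.20 and did not pass (edgeR adjusted p = 0.34). It passed with only the 4 libraries compared (edgeR adjusted p = 0.0247) and without AF9 knockdown replicate 1 (0.0231) or 2 (0.0207). With the GC correction the LDHA difference was -0.41 (edgeR adjusted p = 0.145, DESeq2 adjusted p = 0.0432 with the same trend). DESeq2 called LDHB without the GC trend (adjusted p = 0.00757) and with it (adjusted p = 0.0413). In edgeR the LDHB call was lost with the GC correction (log2 difference 0.41, edgeR adjusted p = 0.134). It was also lost without control replicate 1 (edgeR adjusted p = 0.29) or 2 (0.252), without oxamate replicate 1 (0.45) or 2 (0.0721), and with no filter on low counts (0.0701). MLLT3 differed by -0.02 (edgeR adjusted p = 0.916) and KLF2 by -0.39 (edgeR adjusted p = 0.227), and neither passed. The GC correction moved MLLT3 to -0.37 (edgeR adjusted p = 0.11) and KLF2 to -0.09 (0.779). In the GC-corrected fit MLLT3 passed as lower under oxamate without AF9 knockdown replicate 1 (edgeR adjusted p = 0.00172) or 2 (0.00182).

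Among the genes past the threshold named for this comparison, PRRG3 had the steepest fall here too. It went to a mean of 4.61 CPM from 42.8 CPM in control (log2 difference -3.21, standard error 0.158, edgeR adjusted p = 1.54e-05). IGFBP1 (Entrez 3484; chromosome 7, 45888488 to 45893660), a secreted binding protein of insulin-like growth factors, fell from 16.6 and 20.1 CPM to 3.77 and 4.94 CPM (log2 difference -2.08, standard error 0.19, edgeR adjusted p = 0.00354). The transcription factor gene ARNT2 fell by 1.76, SERPINE1 by 1.58, IER3 by 1.48, the lipase inhibitor gene ANGPTL4 by 1.47, the lysosomal gene CD68 by 1.44 and the antigen presentation gene HLA-B by 1.43. Among the 8 largest rises were the SET domain gene SETDB2 (1.81), the G protein regulator gene RGS5 (1.77), the stress-induced gene NIBAN1 (1.48), the calcium channel subunit gene CACNB2 (1.44) and GDAP1 (1.36). The phosphodiesterase gene PDE7B (1.30), the cholesterol esterification gene SOAT1 (1.25) and CHAC2 (1.24), a glutathione-degrading enzyme gene, rose as well. Without oxamate replicate 1 or 2, PRRG3 kept its size (-3.24 and -3.19) but missed the threshold (edgeR adjusted p = 0.0517 and 0.0538). In the robust fit SERPINE1 (edgeR adjusted p = 0.0964) and GDAP1 (0.0685) lost their calls, and GDAP1 also in DESeq2 (adjusted p = 0.0631).

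The same 5 lists were lower under oxamate by camera with its preset correlation, and again all 5 calls were lost with an estimated correlation. Immediate early genes had 15 of 30 members lower and 0 higher (24 lower adjusted over the list alone), with a median of -0.57 (camera adjusted p = 2.55e-10; adjusted p = 0.663 with an estimated correlation). ETV5 (-1.42), IER3, the phosphatase gene DUSP1 (-1.23) and JUNB (-1.02) were lower. Glycolysis and lactate genes had 10 of 33 members lower and 2 higher (21 and 2 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.000109; adjusted p = 0.663 with an estimated correlation). The glucose transporter gene SLC2A1 (-0.85), the aldolase gene ALDOA (-0.74) and BSG (-0.74) were lower, and SLC16A1, a lactate transporter gene, rose by 0.56. In edgeR the GC correction moved BSG to -0.46, ALDOA to -0.46 and SLC16A1 to 0.33 and ended their calls (edgeR adjusted p = 0.102, 0.119 and 0.114). DESeq2 with the same trend called BSG and ALDOA (adjusted p = 0.000764 and 0.019), while SLC16A1 lay at 0.05. Hypoxia response genes had 11 of 34 members lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 0.000109; adjusted p = 0.693 with an estimated correlation). The carbonic anhydrase gene CA9 (-1.18), BHLHE40 (-1.13), SLC2A1 and the collagen hydroxylase gene P4HA2 (-0.75) fell.

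Mesenchymal and invasion genes had 8 of 29 members lower and 0 higher (8 lower and 1 higher adjusted over the list alone), with a median of -0.29 (camera adjusted p = 0.00025; adjusted p = 0.663 with an estimated correlation). They included the integrin gene ITGA5 (-1.14), TGFBI (-1.10), PLAUR (-0.90) and LOXL2 (-0.89). Histone genes had 4 of 22 members lower and 0 higher (4 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.00059, and 0.663 with an estimated correlation). This list, fixed beforehand as a sign of library preparation, included H1-2 (-1.38), H1-4 (-2.21), H2BC11 (-1.38) and H2BC21 (-1.01). DESeq2 gave no adjusted p for H1-4 or H2BC11, and 42 of 46 listed histone genes had a mean under 1.5 CPM. The GC-corrected medians of these lists were -0.50, -0.30, -0.49, -0.30 and -0.60 in the order given. Lists fixed as markers of other cell types had medians of -0.266 for basal breast epithelium and -0.225 for fibroblasts without passing (camera adjusted p = 0.0917 and 0.334). With the GC correction they were -0.337 and -0.087. The leukocyte list, with 6 tested, had a median of -0.141 before and 0.118 after the correction and passed neither time (camera adjusted p = 0.593 and 0.923).

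**Figure D4:**
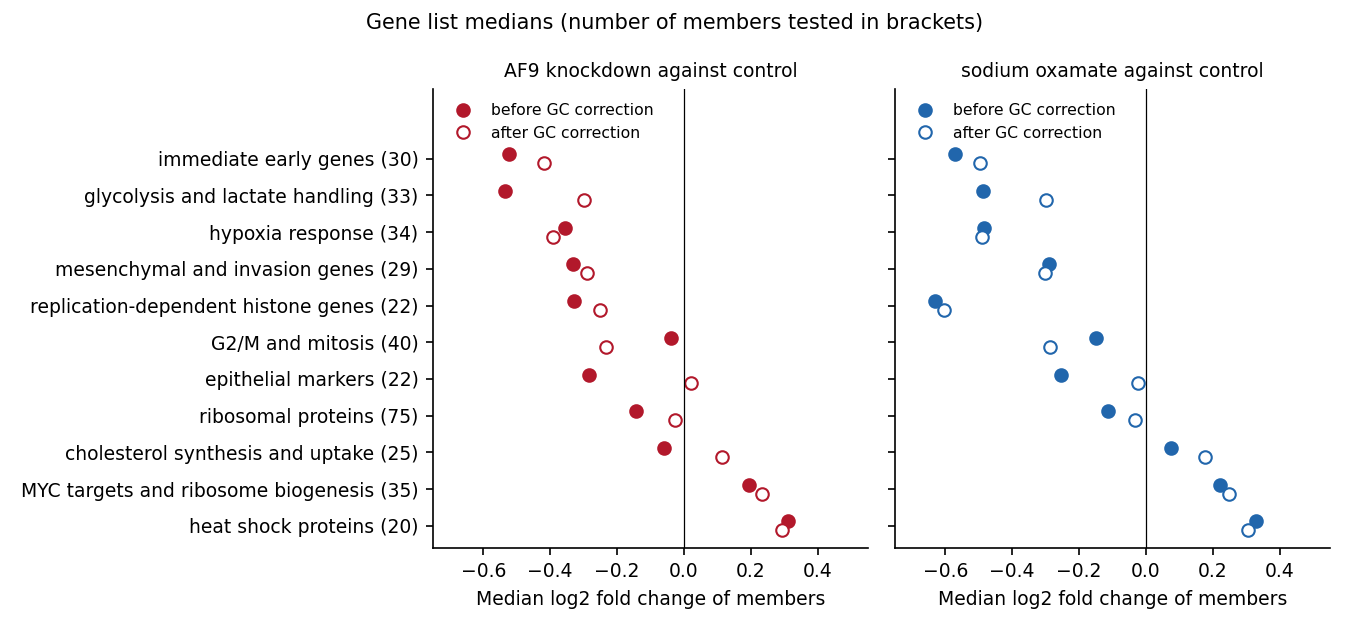
Median log2 fold change (x axes) of the tested members of 11 fixed gene lists (y axis, members tested in brackets) for AF9 knockdown and sodium oxamate against control, before (filled) and after (open) the GC correction. Immediate early genes lie at -0.52 and -0.42 in the knockdown and at -0.57 and -0.50 under oxamate.

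In all, 659 genes were higher and 631 lower under oxamate by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, of which 60 and 58 changed at least 2-fold. With no scaling beyond library totals the split was 77.5% higher against 51.1% with TMM, and the median of all genes lay at 0.126 in place of 0.018. The counts fell to 1 higher and 6 lower with no filter on low counts and to 0 and 0 without oxamate replicate 1 or replicate 2 (1447 and 4148 genes at an unadjusted p below 0.05). They were 9 and 38 without control replicate 1, 8 and 14 without control replicate 2, 2530 and 2437 without AF9 knockdown replicate 1, 2570 and 2426 without AF9 knockdown replicate 2, and 2593 and 2463 with only the 4 libraries compared. Of the 42 named genes past the threshold, 39 lost the call with the GC correction (all but PRRG3, IGFBP1 and H1-2). Of these 39, 35 stayed within 1.5 times their log2 difference, such as ETV5 at -1.43, P4HA2 at -0.75 and ARNT2 at -1.66, and 34 were called by DESeq2 with the same trend. Of the 42, 18 lost the call without control replicate 1, 29 without control replicate 2, 36 with no filter on low counts and all 42 without either oxamate library.

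Both comparisons used the same 2 control libraries, and many genes passed in both. In total 627 genes were higher and 574 lower in both, against 110.6 and 98.4 for independent lists of these sizes, and 0 genes passed in opposite directions. Higher in both were OGT, the enzyme that adds N-acetylglucosamine to proteins (1.43 in the AF9 knockdown and 1.20 under oxamate), the oxidised lipoprotein receptor gene OLR1 (1.13 and 1.05), the protease inhibitor gene SPINK5 (1.03 and 0.96), the cholesterol synthesis gene HMGCS1 (1.03 and 0.94) and NIBAN1 (1.02 and 1.48). Lower in both were PRRG3, H1-2, ITGB4 (-1.38 and -1.39), the signalling adaptor gene GAB2 (-0.99 and -0.94) and the mucin gene MUC1 (-0.85 and -1.18). Of the genes called in both by edgeR, 1 (PRRG3) remained with the GC correction. The correction moved HMGCS1 to 0.59 and 0.61, OLR1 to 0.70 in the knockdown and MUC1 to -0.38 in the knockdown. With it H1-2 was at -0.91 and -1.16, OGT at 1.07 and 0.92, NIBAN1 at 0.83 and 1.34 and GAB2 at -0.77 and -0.78. DESeq2 with the same trend still called every gene named here as higher or lower in both. The largest of its adjusted p-values was 0.0322, for MUC1 in the knockdown. The log2 differences of the comparisons correlated across genes at r = 0.811, against a mean of 0.511 in 20 simulations of unchanged groups set against the same controls, and their covariance was 0.194 against 0.0271, a difference of 0.167. With the GC correction r was 0.723 and the covariance 0.11, a difference of 0.0826 from the simulated value. The simulated groups carried no GC trend, and the GC-corrected fit, run on the same simulated counts, gave the same means as the uncorrected fit. The controls were too few to split, so part of the excess may come from the shared control libraries. The number called in both was 26 without control replicate 1, 15 without control replicate 2, 4152 without AF9 knockdown replicate 1, 3089 without AF9 knockdown replicate 2 and 0 without oxamate replicate 1 or 2.

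The direct comparison of sodium oxamate with AF9 knockdown asked where the treatments differ. By edgeR, 0 genes were higher and 0 lower, with 706 genes at an unadjusted p below 0.05. DESeq2 called 1 gene higher and 7 lower, and with the GC trend 7 and 11. The genes that follow have the smallest p-values and are not past the threshold in the edgeR fit of all 6 libraries. IGFBP1 was at 3.77 and 4.94 CPM under oxamate and 12.1 and 13.1 CPM in the knockdown (log2 difference -1.54, edgeR adjusted p = 0.122, DESeq2 adjusted p = 3.24e-06). TULP3, a cilium trafficking gene, was at 21.2 and 24.0 against 41.7 and 58.5 CPM (log2 difference -1.15, edgeR adjusted p = 0.171, DESeq2 adjusted p = 4.6e-06). In edgeR, IGFBP1 and TULP3 passed with only the 4 libraries compared (adjusted p = 0.0173 and 0.0373), and also without either control library. Across the alternatives their log2 differences ran from -1.75 to -1.35 and from -1.37 to -0.89. The arrestin-like gene ARRDC3 differed by -0.79 (DESeq2 adjusted p = 0.000413) and the oncostatin M receptor gene OSMR by -0.61 (DESeq2 adjusted p = 0.0126). The aldo-keto reductase gene AKR1C2, at 47.1 and 36.6 against 23.9 and 18.6 CPM, differed by 0.98 (edgeR adjusted p = 0.428, DESeq2 adjusted p = 0.000702), the kinase gene MTOR by 0.51, the amino acid transporter gene SLC36A1 by 0.86 and FSD1 by 0.89. Across the alternatives the log2 difference ran from 0.78 to 1.17 for AKR1C2, -0.83 to -0.66 for ARRDC3 and -0.66 to -0.55 for OSMR. It ran from 0.453 to 0.555 for MTOR, 0.71 to 1.00 for SLC36A1 and 0.78 to 0.97 for FSD1. MLLT3 differed by 0.62 (edgeR adjusted p = 0.741) and KLF2 by 0.21 (edgeR adjusted p = 0.903). With the GC correction the MLLT3 difference was 0.74 (edgeR adjusted p = 0.307, DESeq2 adjusted p = 0.000256). EIF3CL, which has a near-identical copy in EIF3C, is uncertain: it was at 0 CPM in both oxamate libraries, 5.83 and 4.80 CPM in the knockdown, and 0 and 2.32 CPM in control.

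Among the fixed lists, targets of the oxidative stress factor NRF2 were higher under oxamate than in the AF9 knockdown (26 members, median 0.19, camera adjusted p = 2.64e-06; adjusted p = 0.28 with an estimated correlation), and endoplasmic reticulum chaperones were lower (25 members, median -0.21, camera adjusted p = 1.78e-05; adjusted p = 0.963 with an estimated correlation). No member of either list passed over all genes tested by edgeR, and adjusted over the list alone 1 NRF2 target (AKR1C2) and 0 chaperone genes did. The NRF2 targets with the smallest p-values were AKR1C2, SRXN1 (log2 difference 0.35), ME1 (0.33) and AKR1C1 (1.78, at under 2 CPM in each library). The chaperone genes were DNAJC10 (-0.75, and -1.015 to -0.444 across the alternatives), HSP90B1 (-0.55), HSPA5 (-0.50) and PDIA6 (-0.32). Without AF9 knockdown replicate 1 the comparison gave 640 genes higher and 658 lower, and without replicate 2 it gave 64 and 116; without either control library, 0 and 4.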

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

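All GC corrections, and the crossed pairing, were chosen after the results were seen; the other alternatives were planned. RLE scaling and the robust fit kept each count of genes within 1.5 times its main value and kept MLLT3 and KLF2 on their side of the threshold in the AF9 knockdown, though the robust fit moved 5 named values below it (NRSN1, SPINK6 and SERPINE1 in the knockdown, SERPINE1 and GDAP1 under oxamate), and the GC length and span alternatives kept the GC-corrected counts within 1.5 times, though length correction lost H1-2 under oxamate (edgeR adjusted p = 0.0554). With no scaling beyond totals, 1116 genes were lower in the AF9 knockdown, and 1208 were higher and 351 lower under oxamate. With no filter on low counts, 1 gene was higher and 6 were lower under oxamate, 6 were called in both comparisons and the correlation of fold changes was 0.599. DESeq2 called 957 lower under oxamate, and 1 higher and 7 lower for oxamate against AF9 knockdown. With only the 4 libraries of a comparison, 1181 were lower in the AF9 knockdown, 2593 higher and 2463 lower under oxamate, and 3 lower for oxamate against AF9 knockdown.

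Replicate numbers did not pair the samples: deviations of libraries with the same number correlated at 0.021 and -0.017 with control and at -0.198 between the treated groups. The replicate block gave 331 higher and 330 lower under oxamate, 3 lower for oxamate against AF9 knockdown and 609 in both comparisons; with the GC correction it gave 1 lower in the AF9 knockdown, losing MLLT3 (edgeR adjusted p = 0.123), and lost H1-2 under oxamate (0.0589). The block kept the other counts within 1.5 times, 5, 5 and 2 lists past the threshold and the correlation at 0.811. It moved LDHB under oxamate below the threshold (edgeR adjusted p = 0.064) and IGFBP1 (0.0213) and TULP3 (0.0266) above it for oxamate against AF9 knockdown. The crossed replicate block gave 2 higher and 9 lower genes for oxamate against AF9 knockdown.

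Leaving out 1 library at a time gave 46 to 3322 higher and 55 to 3242 lower genes in the AF9 knockdown, 0 to 2570 and 0 to 2437 under oxamate, and 0 to 640 and 0 to 658 for oxamate against AF9 knockdown. It gave 0 to 4152 genes in both comparisons and correlations of 0.588 to 0.829. MLLT3 ranged from -0.67 to -0.60 in the AF9 knockdown and KLF2 from -0.81 to -0.41. MLLT3 under oxamate (-0.02) changed sign with no scaling beyond totals (0.086) and ranged from -0.071 to 0.025, positive without oxamate replicate 2. With the GC correction it was -0.37; it passed in none of these, but did in the GC-corrected fit with either AF9 knockdown library left out.

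With the GC correction the counts were 0 higher and 2 lower in the AF9 knockdown, 0 and 3 under oxamate and 1 in both comparisons, with 3232 and 2699 genes at an unadjusted p below 0.05 in edgeR. DESeq2 with the GC trend gave 329 and 453, 216 and 377, and 7 and 11 for oxamate against AF9 knockdown. Leaving out 1 library from the GC-corrected fit gave 0 to 2539 higher and 1 to 2939 lower genes, 0 to 1762 and 1 to 2169, and 0 to 1361 and 0 to 1116. Lists past the threshold numbered 5, 5 and 2; with an estimated correlation 0, 0 and 0; with the GC correction 9, 10 and 4; and with both 0, 0 and 0. Of 103 named gene values, the GC correction in edgeR moved 78 below the threshold and no filter moved 36. DESeq2 without the GC trend moved 5 below and 5 above the threshold. The smaller counts without 1 library come with fewer samples, and the larger ones without an AF9 knockdown library come without a library of the pair that differed most (chi-square per degree of freedom 43.78); for the other shifts the cause was not tested. Genes near the floor rest on few counts, such as 7 to 31 for ESR1, so small differences in them were not detectable at this depth.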

Other observations

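With the GC correction, further fixed lists passed by camera with its preset correlation in both comparisons against control. Genes of G2/M and mitosis were lower, with 34 of 40 members below 0 in the AF9 knockdown (median -0.23, camera adjusted p = 0.000145) and 36 of 40 under oxamate (median -0.29, camera adjusted p = 4.05e-07). Heat shock proteins were higher, with 18 of 20 and 17 of 20 members above 0 (medians 0.29 and 0.30, camera adjusted p = 0.00036 and 0.000779), as were MYC targets and ribosome biogenesis genes, with 27 of 35 and 29 of 35 (medians 0.23 and 0.25, camera adjusted p = 0.000376 and 0.000351). Cholesterol synthesis genes were higher, with 19 of 25 and 22 of 25 members above 0 (medians 0.12 and 0.18, camera adjusted p = 0.028 and 0.000351). For oxamate against AF9 knockdown, genes of DNA replication (39 of 49 above 0, median 0.07, camera adjusted p = 0.0048) and nuclear oxidative phosphorylation subunits (50 of 62, median 0.06, camera adjusted p = 0.0112) were higher. With an estimated correlation all of these calls were lost (smallest adjusted p = 0.673 in the knockdown, 0.579 under oxamate and 0.895 for these lists of the direct comparison). Before the correction none of the lists named so far passed: in the knockdown and under oxamate the medians were -0.04 and -0.15 for G2/M (camera adjusted p = 0.584 and 0.0852), 0.31 and 0.33 for heat shock (0.115 and 0.0669) and 0.19 and 0.22 for MYC targets (0.222 and 0.0852). The median of the cholesterol list in the knockdown was then -0.06 with a test direction of up, so its median and test differed in sign. Ribosomal proteins, with 75 tested, did not pass before or after the correction in the knockdown (median -0.03 after it, camera adjusted p = 0.355), and neither did epithelial markers (median 0.02, camera adjusted p = 0.921).

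All tests of explanations in this part were chosen after the result was seen, except that of MTAP and CDKN2B, which was written before it. The first pattern is that the fold changes against control followed GC content. Library size is argued against by totals that differ by a factor of 1.015. GC-dependent differences between libraries, as arise in PCR or fragmentation, have support mainly within the oxamate pair. Its replicates differed along GC content at a rho of 0.648, against -0.22 in control and -0.267 in the AF9 knockdown. In edgeR 0.0925% of the calls against control remained after the correction (in DESeq2 13.1% for the AF9 knockdown and 23% for oxamate). The spread of the AF9 knockdown pair adds to that loss. The loss cannot tell library differences from a change by the treatments, since the correction removes a GC trend of either origin. A change of GC-rich and GC-poor genes by both treatments stays open and cannot be told apart from such library differences. Both control libraries lie above the other 4 in GC slope (0.223 and 0.192 log2 units per 10 points of GC against -0.207 to 0.027). The gap within the oxamate pair is 53.7% of the gap between control and the rest, against 36% within the AF9 knockdown pair and 10% within the control pair.

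The second pattern is that immediate early, glycolysis and hypoxia genes were lower in both groups. The GC trend as the whole cause is argued against by the preset-correlation test alone. By camera with its preset correlation, 6 of 6 list tests stayed past the threshold after the correction. Each median lay below 0 by more than the standard error of the mean over members, which treats genes as independent. With an estimated correlation 0 of 6 passed (camera adjusted p = 0.673 in the knockdown and 0.579 under oxamate). Whether that setting can find a changed list with these libraries was not tested. The state of the cultures at harvest, such as density or oxygen, is a candidate explanation: the lists also differed between the AF9 knockdown replicates, with GC-corrected medians of -0.30, -0.24 and -0.63 for replicate 2 minus replicate 1 (the smallest in size was -0.242), against 0.14, 0.11 and 0.23 in the oxamate pair and 0.12, 0.08 and 0.16 in control. An effect of lower AF9 and of oxamate on these genes stays open as an untested biological explanation, since both groups were set against the same 2 control libraries.

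The third pattern is that several luminal and epithelial markers, such as ESR1, GATA3 and CDH1, lay near the floor in libraries labelled MCF7, while 18 of 34 listed luminal and 14 of 27 epithelial members had a mean over 10 CPM. A loss of these genes in a filter or annotation is argued against, because 19 members of the 2 lists are listed with a mean under 1.5 CPM. Cells other than the labelled line were tested with MTAP and CDKN2B, which lie in a segment of chromosome 9p21 that the line is known to lack. MTAP met the bound of 10 CPM set beforehand, at 37 to 44.8 CPM. CDKN2B, at 7.65 to 9.08 CPM, fell short of it and lay above the bound of 1 CPM for their absence. By these bounds the test stayed undecided. CDKN2A, which lies between them and was not part of the test, was at 152 to 209 CPM. Counts per library were 764 to 962 for MTAP, 166 to 191 for CDKN2B and 3356 to 4219 for CDKN2A. In all 6 libraries they argue against cells that lack this segment, as the labelled line is known to. Which cells they are was not tested. No biological explanation was tested, since the pattern was present in all 3 groups.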
